A study of Mus musculus with 4 samples.

How the data were processed

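Gene expression was measured by RNA sequencing in 4 libraries of mouse Th17 cells, which the labels put in 1 group as biological replicates 1 to 4. Replicate numbers were taken from the labels and match those in the file headers. Per the file headers, the authors counted fragments per gene with featureCounts version 1.4.6-p4 on reverse-stranded paired reads (strand option 2), against GENCODE M13, with both ends required to map. The deposited values are raw counts, 1 table per library, with no normalization and no pooling. The deposited tables also give the Length of each gene, its summed exon length in bases, per the file headers. The genome build is mm10 per the labels. The aligner version and read trimming are not given in the sources used here. The recorded command holds no option for reads that map to several places or overlap several genes. Such reads would be left out under the counter's defaults, which lowers the counts of genes with near-identical copies.

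Each table lists 50600 genes. Gene symbols and types came from GENCODE vM21, matched on the identifier without its version; 50376 identifiers matched and 224 had no symbol. Start and end were taken from the exons in the deposited tables. There were no spike-in genes. Total counts ranged from 33123029 to 37746767, so that a count of 3, the floor used for a gene with 0 counts, stood for 0.0795 to 0.0906 CPM. Before values were averaged, libraries were compared in pairs. A chi-square test of their counts gave 4.64 to 7.05 per degree of freedom among replicates 1, 3 and 4 and 48.8 to 54.1 for pairs with replicate 2. No pair was identical or within sampling noise, and each library was counted as 1 sample.

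The design, its tests, the gene lists, the rule for named genes and most alternatives were fixed before the data were examined. It assumed estimated counts with an effective length. The files held whole counts with a summed exon length instead, so counts were used as deposited and TPM was computed here as count over Length, scaled to the same sum in each library. The level of each gene was tested against 1 TPM with an intercept-only edgeR quasi-likelihood fit, with the log of length and library scale as offset. The package's test function takes no intercept-only design, so its F statistic was formed from the fitted deviances. Genes with at least 10 counts summed over the libraries were tested. Each replicate was compared in turn with the other 3 by edgeR's quasi-likelihood test with TMM normalization. Standard errors were derived as the absolute log2 change over the square root of F. Variability was tested as each gene's quasi-dispersion over the trend, in an F test with a robust prior. P-values were adjusted by Benjamini-Hochberg, with a threshold of 0.05. For lists, counts are given over all genes tested and adjusted over the list alone.

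The 32 gene lists covered the Th17, Th1, Th2, Treg and Tfh lineages, Th17-inducing transcription factors, genes linked to pathogenic and non-pathogenic Th17 cells, pan-T cell, naive and central memory, activation and co-inhibitory receptor genes. They also covered CD8, gamma-delta and innate-like T cells, NK, B, myeloid and dendritic, erythroid and platelet, and stromal cells, as well as cell cycle, glycolysis, cholesterol and fatty acid synthesis, the TGF-beta pathway, IL-6 and STAT3, type I interferon, immediate early and heat shock genes. The last were p53 and unfolded protein response genes, mitochondrially encoded mRNA, replication-dependent histones, small RNA without a poly(A) tail, nuclear long non-coding RNA and sex-linked genes. In each replicate comparison, camera tested the 30 lists with at least 3 tested members, with a preset correlation of 0.01 and again with an estimated one. Differences between lists were taken per library on log2(TPM + 0.1) and tested with an exact two-sided sign-flip test, whose smallest p is 0.125 with 4 libraries and 0.25 with 3. List labels were also permuted across genes 100000 times. The spread of a list is the median SD of its members with a mean of at least 1 TPM, set among 10000 random lists drawn from each member's 100 neighbours on either side in mean expression. This gave 29 lists.

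The text names Th17 list members, 10 defining genes of the other subsets (Tbx21, Ifng, Gata3, Il4, Il5, Il13, Foxp3, Il10, Bcl6 and Cxcr5) and the 3 members of each other list with the highest mean TPM. It also names from the 10 protein-coding genes with the highest mean TPM. Among genes past the variability test with a mean of at least 5 TPM it takes the 15 with the largest SD, and for each replicate the 5 largest rises and 5 largest falls among genes past the test with a mean of at least 5 TPM. Genes without a symbol were passed over. Results that need any of 4 particular genes are not reported here, among them 4 results of the design and 1 test of an explanation for replicate 2; the lists and counts still include these genes. Other members named as examples of a list, and genes outside the lists in the closing section, were chosen after their values were seen.

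Tools were R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9. The fits to counts were tested on simulated counts drawn from the real means and library sizes. The sign-flip test was tested on typed values and the permutation of list labels on random normal values. The spread of a list was tested on the real mean levels with random noise of the same size in every gene. For replicate 2 against the other 3 libraries, over 17337 genes, edgeR recovered 98.5% of 200 genes changed 2-fold, with 7.94% false among its calls, and 100% at 4-fold, with 6.10% false. DESeq2 recovered 92.5% and 100%, with 2.12% and 0.990% false. With no gene changed edgeR made 2 calls and DESeq2 1. For the level test over 17337 genes, 3.08% of 200 genes set to 1 TPM were called above it, 89.3% of those set to 2 TPM and 98.0% of those set to 4 TPM. For variability over 17337 genes, 98.5% of 200 variable genes were recovered with 1.01% false. The simulations of level and variability took their spread from a fit that set replicate 2 apart, unlike the tests themselves. The common biological coefficient of variation was 0.0593 in simulated counts with no gene made more variable and 0.181 in the real counts. Rates for variability therefore do not carry over to the real libraries, and those for level may not. The permutation of list labels, on 26 genes, gave a p under 0.05 in 6.75% of 400 null draws, slightly above its nominal rate. In the test of list spread, 3% of 100 unchanged lists and 100% of 20 widened lists lay at or above percentile 95.

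Alternatives covered DESeq2 size factors and the DESeq2 Wald test, no filter and a filter of 100 counts, thresholds of 0.5 and 5 TPM, limma on log2(TPM + 0.1), TPM rescaled without mitochondrial and small RNA genes, pseudocounts of 0.01 and 1, CPM without length correction, medians, a non-robust prior and leaving out each replicate. Removal of each library's trends with GC content and exon length, and thinning to the smallest total, were chosen after seeing the data. A list of 18 keratinocyte genes without the Sprr family was written before its values were read. Ratios of counts carry exact 95% binomial intervals. The text files that accompany the count tables were read only for the assembly.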

Results

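RNA was sequenced from mouse T helper 17 (Th17) cells, CD4 T cells that secrete interleukin 17 (IL-17). The cells were primary cells of the C57BL/6NJ strain, and the labels link a protocol for differentiating CD4 T cells in culture. The 4 libraries form 1 group with no treated or control arm. The labels give 4 biosamples under 1 donor identifier, and do not say whether these came from different animals, so the p-values below measure only the spread between these samples. The file headers carry a time of 72 hr for each library. Total counts were 33123029 in replicate 1, 37507204 in replicate 2, 35314517 in replicate 3 and 37746767 in replicate 4. Between 19572 and 20355 genes had a count in a library. Protein-coding genes held 98.8% to 98.9% of the counts, mitochondrial genes 0.770% to 0.914%, and the 10 most abundant genes of a library 3.91% to 4.16%. The mitochondrial share may be too low, as 6 of the 13 mitochondrially encoded mRNAs had fewer than 10 counts each over the libraries. The assay is named total RNA-seq in the labels, while the title of the library protocol they link names poly(A)+ RNA.

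The first question was which genes these cells expressed, and whether the genes that define Th17 cells were among them. The Th17 cytokines were the most abundant of the Th17 lineage genes. Il17f and Il17a, the cytokines that name the lineage, stood at 2216 ± 1098 and 1846 ± 911 TPM (TPM, the share of a library's transcripts after correction for gene length; mean ± SD, n = 4). Il22, a cytokine acting on epithelia, had 311 ± 92.6 TPM, and the chemokine receptor gene Ccr6 had 191 ± 93.5 TPM. The wide SDs of Il17a, Il17f and Ccr6 came from replicate 2, where they stood at 505, 578 and 51.5 TPM. In the other 3 libraries Il17a had 2293 ± 217, Il17f 2761 ± 145 and Ccr6 238 ± 11.3 TPM (SD, n = 3). On mm10, Il17a (ENSMUSG00000025929.4) spans bases 20730905 to 20734496 and Il17f (ENSMUSG00000041872.9) bases 20777146 to 20790617 of chromosome 1, and Ccr6 (ENSMUSG00000040899.13) spans bases 8236043 to 8257127 of chromosome 17. All 3 are annotated as protein-coding genes.

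**Figure D1:**
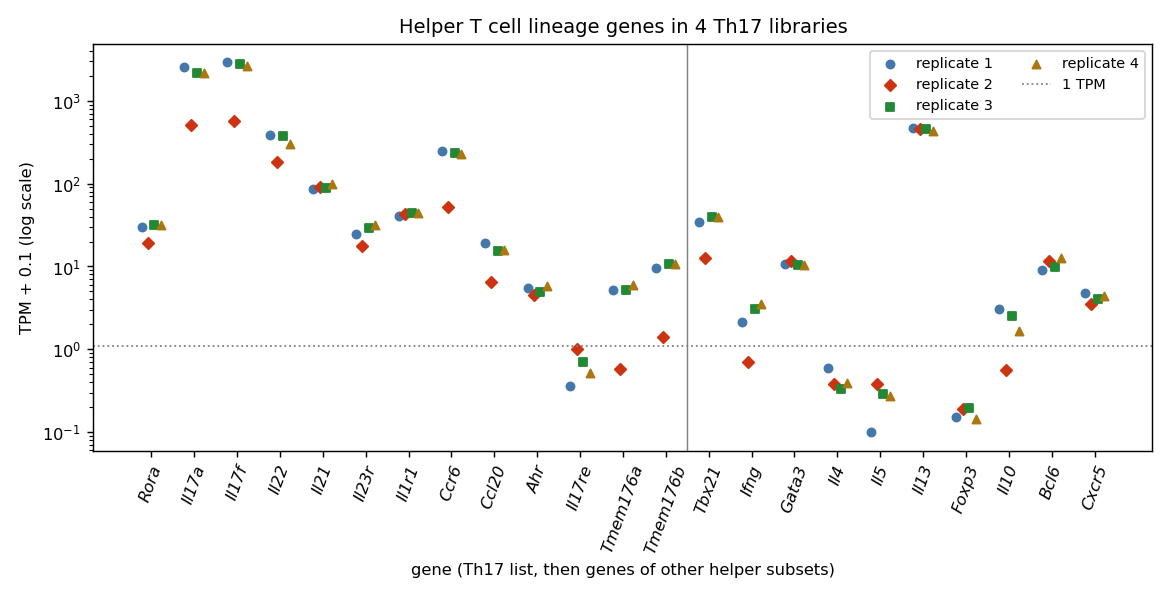
Each point is the level of a gene in 1 library, as TPM + 0.1 on a log axis, for 13 genes of the Th17 list and then for genes of other helper subsets. Il17a stood at 505 TPM in replicate 2 and Tbx21 at 12.7 TPM, while the other 3 libraries averaged 2293 and 37.8 TPM.

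Of 17337 genes tested, 12243 lay above 1 TPM, 2851 below it and 2243 had neither call (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted). In the Th17 list 13 of 14 genes lay above 1 TPM, the same number when adjusted over the list alone. Il21, Il1r1, Rora and Il23r had 91.2 ± 5.18, 43.0 ± 1.67, 28.1 ± 5.96 and 25.7 ± 5.96 TPM. The chemokine gene Ccl20 had 14.2 ± 5.44 TPM, Ahr 5.08 ± 0.559, Tmem176b 8.04 ± 4.50 and Tmem176a 4.18 ± 2.49 TPM. Il17re, an IL-17 receptor subunit gene, lay below 1 TPM at 0.544 ± 0.280 TPM, a call that was lost without replicate 1, 3 or 4 (log2 level −0.64, −0.92 and −0.76). Transcription factors that induce the Th17 state were abundant, with 10 of 11 above 1 TPM, among them Batf at 954 ± 35.3, Bhlhe40 at 669 ± 19.7 and Hif1a at 326 ± 64.7 TPM. All 15 genes of the list linked to pathogenic Th17 cells lay above 1 TPM, led by the chemokine gene Ccl3 at 1303 ± 871 and the growth factor genes Il3 and Csf2 at 915 ± 238 and 528 ± 45.6 TPM. Ccl3 stood at 2607 TPM in replicate 2 and at 868 ± 55.2 TPM in the other 3 libraries. Of the list linked to non-pathogenic Th17 cells, 6 of 8 passed, led by Cd5l, a regulator of lipid metabolism in Th17 cells, at 304 ± 29.9 TPM.

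Genes of other helper subsets were also present. Tbx21, the Th1 regulator, had 31.6 ± 12.8 TPM, and 11 of 12 Th1 genes lay above 1 TPM, while the Th1 cytokine gene Ifng had 2.26 ± 1.25 TPM and lost its call without replicate 3 or 4 (log2 level 1.02 and 0.89). In replicate 2 Tbx21 stood at 12.7 TPM, against 37.8 ± 2.83 TPM in the other 3 libraries. Of 12 Th2 genes 7 passed. Il13, a cytokine of Th2 cells, had 456 ± 16.0 TPM, while Il4 and Il5 lay below 1 TPM at 0.326 ± 0.115 and 0.161 ± 0.118 TPM. Gata3, the Th2 regulator, had 10.8 ± 0.616 TPM. Of 12 regulatory T cell (Treg) genes 10 passed, led by Ctla4 at 1141 ± 480 TPM (422 in replicate 2), whereas Foxp3, the Treg regulator, lay below 1 TPM at 0.0696 ± 0.0256 TPM. Il10 had 1.86 ± 1.10 TPM and no call (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.0554), but lay above 1 TPM without replicate 2 (log2 level 1.21). It also did so with no filter on counts (0.89) and with TPM rescaled without mitochondrial and small RNA genes (0.94). Of 10 follicular helper (Tfh) genes 9 passed. Bcl6, their regulator, had 10.7 ± 1.66 TPM and the homing receptor gene Cxcr5 4.07 ± 0.501 TPM.

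Genes of a dividing, activated T cell were high. All 14 pan-T cell genes, 10 naive and central memory genes, 12 activation genes, 17 cell cycle genes, 14 glycolysis genes and 17 genes of cholesterol and fatty acid synthesis lay above 1 TPM. Il2, the T cell growth factor gene, had 3050 ± 113 TPM, the glycolytic enzyme gene Ldha 4317 ± 447 and the ribonucleotide reductase gene Rrm2 493 ± 8.46 TPM. All 10 genes of the TGF-beta pathway and all 8 of the IL-6 and STAT3 pathway, the signals that drive Th17 differentiation, also passed, with Jak2 at 407 ± 72.4 TPM. So did all 10 immediate early and heat shock genes, led by Junb at 1299 ± 42.3 TPM, and all 10 genes of the p53 and unfolded protein responses, led by Cdkn1a at 1221 ± 106 TPM. Co-inhibitory receptor genes passed in 6 of 8 cases and type I interferon response genes in 7 of 12. The most abundant protein-coding genes outside the mitochondria were Rplp1 at 10173 ± 1055, Eef1a1 at 6965 ± 853 and Rplp0 at 6501 ± 476 TPM, all parts of the translation machinery.

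Markers of other cell types were sparse. Above 1 TPM lay 4 of 7 CD8 T cell genes, 1 of 8 gamma-delta and innate-like T cell genes, 1 of 7 natural killer (NK) cell genes, 2 of 10 B cell genes, 3 of 14 myeloid genes and 3 of 8 stromal genes. The highest of these were Ighm, an immunoglobulin gene, at 64.2 ± 5.37 TPM, Ebf1, a B lineage regulator, at 42.5 ± 2.17 TPM and Cd8b1 at 42.0 ± 7.49 TPM. Of the replication-dependent histone genes 7 of 16 lay above 1 TPM, and 6 when adjusted over the list alone; for every other list the number was the same when adjusted over the list alone. Of the small RNA genes without a poly(A) tail 3 of 11 passed, led by Rpph1 at 10.5 ± 2.92 TPM, and of the nuclear long non-coding RNAs 4 of 6, led by Gas5 at 218 ± 8.41 TPM. Of the 13 mitochondrially encoded mRNAs 7 passed, led by mt-Co1 at 6514 ± 628 TPM; the other 6 (mt-Nd3, mt-Nd4l, mt-Co2, mt-Co3, mt-Atp6 and mt-Atp8) had fewer than 10 counts summed over the libraries. The recorded counting command sets no option for reads that map to several places, so low counts of genes with near-identical copies are uncertain.

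The second question was whether the Th17 list stood above the lists of the other helper subsets. As means over lists, the Th17 genes lay 1.18 ± 0.27 above the Th1 genes, 2.71 ± 0.43 above the Th2 genes and 0.98 ± 0.33 above the Treg genes on the log2 scale, each in 4 of 4 libraries (mean ± SD, n = 4, exact two-sided sign-flip p = 0.13 for each). That p is the smallest that 4 libraries allow. They lay 0.33 ± 0.28 above the Tfh genes in 3 of 4 libraries (n = 4, exact p = 0.25), with −0.09 in replicate 2. When the list labels were permuted across genes, which are not independent replicates, none of the 4 differences passed (permutation p = 0.323, 0.0901, 0.512 and 0.81; Benjamini-Hochberg adjusted p = 0.646, 0.361, 0.682 and 0.81). The sizes depended on how lowly expressed members were treated: with only members of at least 1 TPM on average they were 1.23, 0.67, 0.18 and 0.79, that from the Treg genes no longer lying above 0 in every library (0.18 ± 0.41, n = 4, exact p = 0.625), and as differences of medians 0.32, 2.47, 1.91 and 1.02. Without length correction the difference from the Tfh list was 0.07 ± 0.29 (n = 4, exact p = 0.625).

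The third question was how far each replicate stood from the others, gene by gene. Replicate 2 stood furthest from the others, with lower Il17a, Il17f and Ccr6 and higher Ccr7 and Tcf7. Il17a was lower by a log2 change of −2.12 ± 0.14 (SE), Il17f by −2.20 ± 0.06 and Ccr6 by −2.14 ± 0.06. Ctla4, an inhibitory receptor gene, was lower at −1.65 ± 0.05. Tcf7, which encodes the naive and memory T cell factor TCF1, was higher at 0.85 ± 0.04, and Ccr7, a lymph node homing receptor gene, at 1.03 ± 0.05. In edgeR quasi-likelihood tests the Benjamini-Hochberg adjusted p-values were 0.00169 for Il17a, 1.8e-13 for Il17f, 2.26e-15 for Ccr6, 2.16e-15 for Ctla4, 6.27e-12 for Tcf7 and 8.63e-13 for Ccr7. In all, 3907 of 17337 genes differed in replicate 2, 2024 higher and 1883 lower. Of them 784 changed over 2-fold, 325 higher and 459 lower, and the median absolute log2 change was 0.39. Each such test compared 1 library with 3, not conditions, and assumed that the lone library varies like the others.

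**Figure D2:**
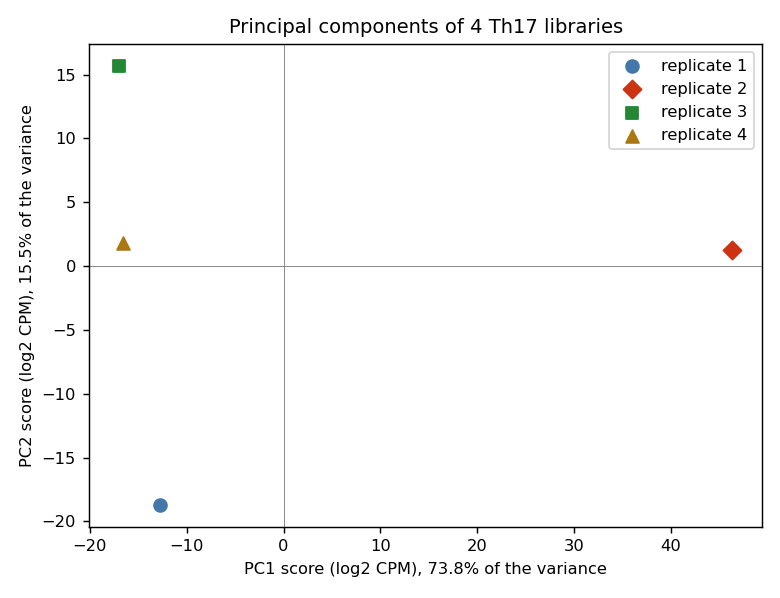
Scores of the 4 libraries on the first principal components of log2 CPM, counts scaled to library size, over 12599 genes; the axes give each component's share of the variance. Replicate 2 lies at 46.3 on the first component, which holds 73.8% of the variance, and the other libraries lie between −17.0 and −12.7.

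The genes furthest apart in replicate 2 were of the Sprr family, small proline-rich proteins of the cornified envelope of epithelia. Sprr2d (ENSMUSG00000042212.3, chromosome 3, bases 92339140 to 92340873) had 2640 counts in replicate 2 and 1, 2 and 0 in replicates 1, 3 and 4. Its ratio to the other libraries per total count was 2491, with a 95% counting interval of 852 to 12088. For Sprr1a the counts were 1607 against 1, 1 and 0, with a ratio of 2275 (interval 629 to 18799). Sprr2g had 1178 against 1, 0 and 0, with a ratio of 3335 (interval 597 to 131834). Sprr2f had 149 against 0 in each other library, which made it at least 141-fold higher against a floor of 3 counts over those libraries, and Sprr2h had 2735 against 0, 5 and 2. These intervals and floors cover counting error only. The Sprr2 genes are close paralogs, so the split of reads among them is uncertain. The 5 largest falls among genes of at least 5 TPM on average were Mmp7, Itgb8, Cdh17, Il33 and Serpina3g. Mmp7, a matrix protease gene, had 1 count in replicate 2 against 85, 150 and 157, the other libraries being 138 times higher per total count (interval 24.7 to 5483). Itgb8, an integrin gene involved in TGF-beta activation, was lower at −3.93 ± 0.15, Cdh17 at −3.28 ± 0.17, the alarmin gene Il33 at −3.12 ± 0.13 and Serpina3g at −3.05 ± 0.32 (log2 ± SE).

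Within the Th17 list 8 of 14 genes were lower in replicate 2, 0 were higher and 6 had no call. Adjusted over the list alone 8 were lower and 1 higher (Il17re, at 1.16 ± 0.43), the same 1 that was higher at an unadjusted p under 0.05. Il17re was called higher without replicate 3 (1.48), with no filter on counts (1.15) and with a filter of 100 summed counts (1.15). DESeq2 called 9 lower and 0 higher. Tmem176a and Tmem176b were lower at −3.42 ± 0.27 and −2.89 ± 0.23, Ccl20 at −1.31 ± 0.20, Rora at −0.63 ± 0.05 and Il23r at −0.62 ± 0.12. Il21, Il1r1 and Ahr had changes of 0.08, 0.04 and −0.18 with no call, and Il22 one of −0.89 ± 0.22 (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.142), which was called lower by DESeq2 and without replicate 1 or 4 (−0.82 and −0.99). The list as a whole was lower by camera, a test of a list against other genes (adjusted p = 4.46e-23 with a preset correlation of 0.01). That call was lost, at adjusted p = 0.232 with an estimated correlation. Glycolysis fell as a list in replicate 2, with 14 of 14 genes lower by edgeR and by DESeq2, the glucose transporter gene Slc2a1 at −0.84, Gpi1 at −0.62, Tpi1 at −0.56 and Ldha at −0.25 (camera adjusted p = 1.22e-12). That list had adjusted p = 0.232 with an estimated correlation. The estimate was −0.04 for both lists, under the preset 0.01, so correlation among members was not what raised these p-values. Of the other lists that camera called in replicate 2, only the Tfh (0.11), CD8 T cell (0.61) and interferon (0.39) lists had an estimate above the preset one. With an estimated correlation camera takes its degrees of freedom from the libraries, which are few, and not from the number of genes. That raises the p-value whatever the correlation, and no list passed in replicate 2. In simulated counts 5 of 5 lists raised 2-fold were still called with an estimated correlation.

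Genes of the other helper subsets were lower more often than higher in replicate 2. Of 12 Th1 genes 8 were lower, among them Tbx21 at −1.51 ± 0.12, Ifng at −2.13 ± 0.57 and Il18rap at −1.77. The exception was Eomes, a T-box factor of cytotoxic and memory T cells, higher at 3.10 (camera adjusted p = 0.00458, and adjusted p = 0.327 with an estimated correlation). Of 12 Treg genes 6 were lower, such as Ctla4 and the IL-2 receptor gene Il2ra at −0.53 ± 0.04, both also induced by T cell activation, and 1 was higher, Lrrc32, which presents latent TGF-beta, at 1.24 (camera adjusted p = 0.000971, and adjusted p = 0.327 with an estimated correlation). Of 10 Tfh genes 5 were lower, such as Pdcd1 at −0.69 ± 0.05 and Slamf6 at −0.83, and 2 were higher, Sh2d1a at 0.28 and Cd200 at 0.15, with 3 higher when adjusted over the list alone and 4 without replicate 4 (camera adjusted p = 0.0237, and adjusted p = 0.440 with an estimated correlation). Of 10 Th2 genes tested 5 were lower, such as Ccr4 at −0.53 ± 0.05 and Areg at −0.67, while Il13 had 0.08 ± 0.05 with no call (camera adjusted p = 0.0928). Of 8 co-inhibitory receptor genes Pdcd1, Lag3 at −0.65 and Ctla4 were lower and Cd274 was higher at 0.48 (camera adjusted p = 0.00423, and adjusted p = 0.327 with an estimated correlation).

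The list linked to pathogenic Th17 cells divided, with 6 of 15 genes higher and 6 lower in replicate 2. The chemokine genes Ccl3, Ccl4 and Ccl5 were higher at 1.65 ± 0.05, 2.37 and 0.68, Il3 at 0.73 ± 0.07 and Csf2 at 0.29 ± 0.05. Cxcl3, Lgals3 and Tbx21 were lower at −1.44, −1.36 and −1.51. Its median was −0.15 and its mean −0.03, while camera gave the direction up (adjusted p = 0.0230, and adjusted p = 0.351 with an estimated correlation). Of the 8 genes linked to non-pathogenic Th17 cells 4 were lower, with Il9 at −2.69 ± 0.24, Il10 at −2.23 ± 0.64, the IL-1 antagonist gene Il1rn at −1.56 ± 0.09 and Maf at −0.70. Ikzf3 was higher at 0.98, which DESeq2 did not call (camera adjusted p = 0.00215, and adjusted p = 0.327 with an estimated correlation). Among the 11 Th17-inducing factors 3 were higher, with Hif1a at 0.59 ± 0.04, and 4 lower, while Batf, Stat3 and Irf4 had changes of −0.03, −0.02 and −0.08 with no call (camera adjusted p = 0.937). Of 8 IL-6 and STAT3 genes 4 were higher, such as Socs3 at 0.40 and Pim1 at 0.34 ± 0.05, and Jak2 was lower at −0.51 ± 0.04 (camera adjusted p = 0.159). Of 10 TGF-beta genes 2 were higher, among them Smad7 at 0.45, and 2 lower, Tgfb1 and Skil at −0.26 ± 0.05 and −0.18, with 1 lower by DESeq2, without replicate 1 and with GC content and exon length trends removed (camera adjusted p = 0.628).

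Naive and central memory genes were higher in 6 of 10 cases in replicate 2, among them Ccr7, Tcf7, S1pr1 at 0.36 and Satb1 at 0.30 ± 0.04, while 2 were lower, among them Foxp1 at −0.24 (camera adjusted p = 0.00191, and adjusted p = 0.327 with an estimated correlation). Of 12 activation genes 6 were higher, such as Cd69 at 0.53 and Nr4a1 at 0.43 ± 0.05, and 3 lower, Tnfrsf9 at −0.82, Egr2 at −0.68 and Tnfrsf4 at −0.28 ± 0.05 (camera adjusted p = 0.907). Pan-T cell genes had 2 higher, 2 lower and 10 without a call, with Cd4 at 0.01, and 1 higher without replicate 1 (camera adjusted p = 0.926). Cell cycle genes were lower in 6 of 17 cases by small amounts, such as Mki67 at −0.22 (camera adjusted p = 0.0619), and genes of cholesterol and fatty acid synthesis in 5 of 17, such as Scd2 at −0.37 ± 0.04, with 7 lower when adjusted over the list alone and Hmgcs1 higher at 0.14 ± 0.05 (camera adjusted p = 0.0647). In the p53 and unfolded protein response list the p53 targets Cdkn1a, Mdm2, Bbc3, Bax and Ccng1 were higher, with Mdm2 at 0.60 and Cdkn1a at 0.28 ± 0.05. The stress genes Ddit3, Trib3, Hspa5 and Xbp1 were lower, with Trib3 at −1.23 and Hspa5 at −0.41 ± 0.04; 5 were lower when adjusted over the list alone (camera adjusted p = 0.984).

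Type I interferon response genes also divided in replicate 2. Oas1a, an antiviral RNA sensor gene, was higher at 4.82 ± 0.12, Usp18, a negative regulator of interferon receptor signalling, at 3.80 and Bst2 at 0.27 ± 0.06, a call lost at 0.16 with GC content and exon length trends removed, while Isg15, Ifit1, Irf7 and Mx1 were lower, Isg15 at −1.50; 5 were lower when adjusted over the list alone. The median was −1.04 and the mean −0.81, while camera gave the direction up (adjusted p = 0.0270, and adjusted p = 0.635 with an estimated correlation). Of 10 immediate early and heat shock genes 4 were higher, such as the chaperone gene Hspa1a at 1.19, and 2 lower, Jun at −0.39 and Egr1 at −0.18 ± 0.05, with 5 lower when adjusted over the list alone, 5 without replicate 3 and 4 without replicate 4 (camera adjusted p = 0.949). Its median was −0.16 and its mean 0.07. Median and mean also had opposite signs for the p53 and unfolded protein response, Th17-inducing, mitochondrial, small RNA, nuclear long non-coding RNA and sex-linked lists, none of which camera called. In the stromal list both were negative while camera gave the direction up, also without a call.

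Among markers of other cell types, CD8 T cell genes were lower in replicate 2. Of 5 CD8 T cell genes tested 4 were lower, Klrc1 at −2.71 ± 0.26, Crtam at −2.30 ± 0.13, the perforin gene Prf1 at −1.74 and Cd8b1 at −0.47 ± 0.11 (camera adjusted p = 2.23e-06, and adjusted p = 0.351 with an estimated correlation). Cd8a, which encodes the other CD8 chain, had too few counts to be tested. Among gamma-delta genes 1 of 4 tested was higher, Sox13 at 1.02 ± 0.21 (camera adjusted p = 0.309), and among NK genes 1 of 2 was lower, Klre1, with 0 counts in replicate 2 against 17, 8 and 11, at least 4.24-fold lower against a floor of 3 counts. In the B cell list edgeR called 0 of 9 tested genes, with 1 at an unadjusted p under 0.05, and DESeq2 called 0, while 1 was higher without replicate 3 or 4 and after thinning to the smallest total (camera adjusted p = 0.758). Of 8 myeloid genes tested Flt3, a receptor of early progenitors and dendritic cells, was higher at 3.58 and Adgre1 lower at −0.54 ± 0.15, with 2 higher when adjusted over the list alone (camera adjusted p = 0.0540). Of 5 stromal genes Dcn and Pecam1 were higher at 1.30 ± 0.13 and 0.29 ± 0.09 and Pdgfrb lower at −1.26 ± 0.27 (camera adjusted p = 0.628). The mitochondrial, small RNA and sex-linked lists had 0 genes called by edgeR, with 1, 0 and 0 at an unadjusted p under 0.05 and 0, 0 and 1 called by DESeq2 (camera adjusted p = 0.926, 0.984 and 0.611). The counts of 0 depended on single libraries: without replicate 1 edgeR called 4 of the 5 sex-linked genes higher and 1 lower, and of the 7 mitochondrial genes tested it called 2 higher without replicate 1, 1 higher and 1 lower without replicate 3 and 4 higher without replicate 4. With no filter on counts it called 2 of 9 mitochondrial genes higher, while the small RNA list kept 0 in each of these settings. The 4 Y-linked genes together had 8302 counts in replicate 1 and 9085 in replicate 2, against 52 and 48 in replicates 3 and 4. Without replicate 1 the comparison of sex-linked genes thus followed that division. Of the histone genes Hist1h1c was higher at 0.49 ± 0.14, with 2 higher without replicate 1 or 3 (camera adjusted p = 0.159), and of the nuclear long non-coding RNAs Snhg1 was higher at 0.23 ± 0.05 and Neat1 lower at −0.34, with 2 higher without replicate 1 or 4 (camera adjusted p = 0.937). DESeq2 did not call Klre1, Adgre1 or Pecam1. For every list not named here with its own number, the count adjusted over the list alone was the same as that over all genes.

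**Figure D3:**
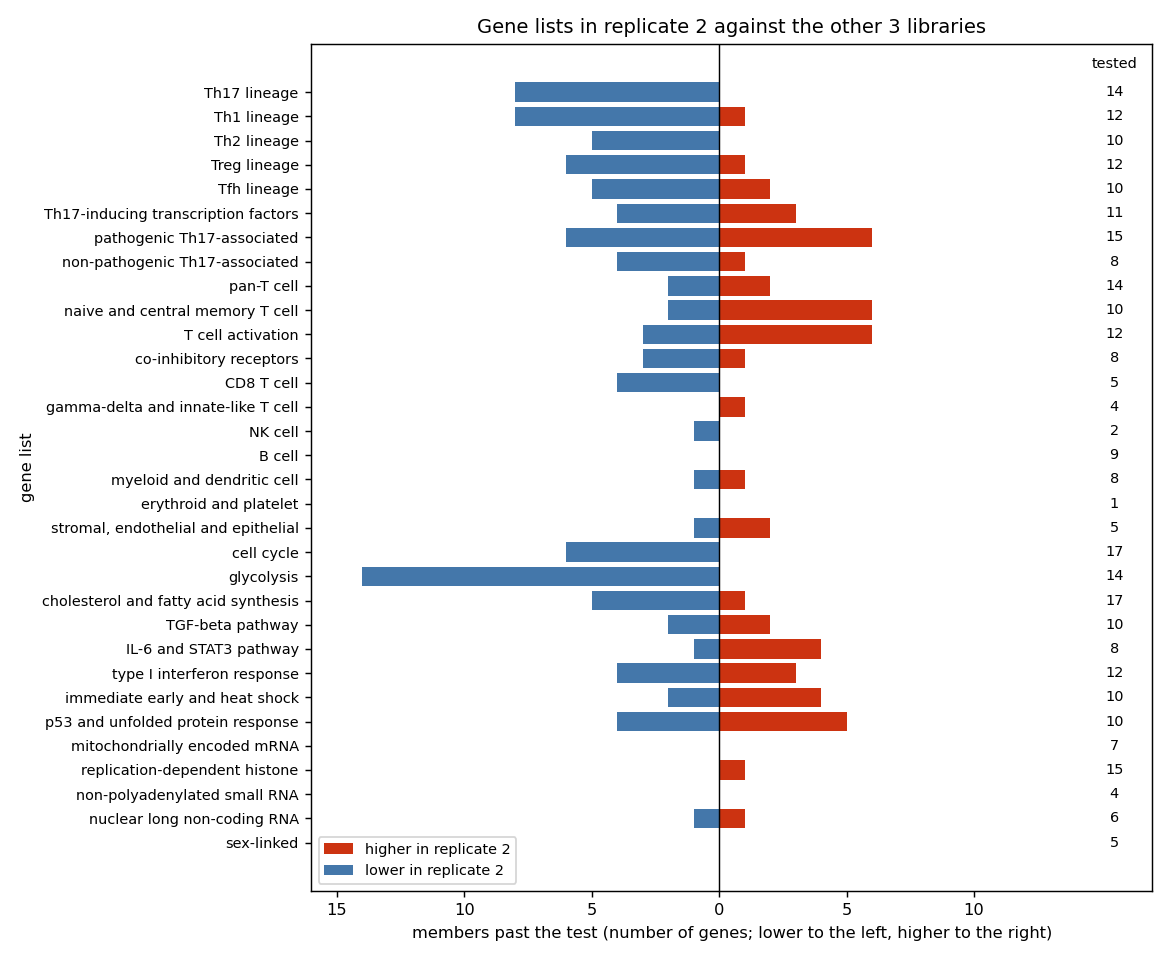
Bars give, for each gene list, the number of members past the edgeR test in replicate 2 against the other 3 libraries, lower to the left and higher to the right; the number tested stands at the right. Glycolysis has 14 of 14 members lower and the Th17 list 8 of 14.

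Replicates 1, 3 and 4 differed little from the rest. Against the other 3 libraries edgeR called 0 genes in each, with 166, 257 and 128 at an unadjusted p under 0.05, while DESeq2 called 2, 15 and 3. Replicate 2 was then among the libraries compared with. Without it, edgeR called 68 genes in replicate 1, 108 in replicate 3 and 9 in replicate 4. Replicate 1 was then the only library with low Xist and high Y-linked counts, so its 68 genes cannot be told apart from that division. Glycolysis and the CD8 T cell list were higher in replicate 1 by camera (adjusted p = 0.0415 and 0.0274), as was the interferon list (adjusted p = 0.0274); all 3 had adjusted p = 0.756 with an estimated correlation. In replicate 4 camera called the Th17, glycolysis and mitochondrial lists higher (adjusted p = 0.05, 0.0190 and 0.0159) and the histone and sex-linked lists lower (adjusted p = 0.0190 for both); all 5 had adjusted p = 0.856 with an estimated correlation. No list was called in replicate 3, though the sex-linked list had a median log2 change of −6.45 there, against −6.94 in replicate 4. That list joins Xist, high in both replicates, with Y-linked genes, low in both, so it did not fall as a whole. The comparisons of replicates 1, 3 and 4 had replicate 2 on the other side: in replicates 1 to 4 the median was 692, 478, 671 and 676 TPM for glycolysis and 4.49, 1.22, 3.98 and 4.29 TPM for the CD8 T cell list. For the Th17 list it was 35.5, 30.8 and 37.8 TPM in replicates 1, 2 and 4 and higher still in replicate 3.

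The last question was which genes varied most among the 4 libraries. Sex-linked and Sprr genes did. Xist, the RNA that silences an X chromosome (ENSMUSG00000086503.3, X chromosome, bases 103460375 to 103483217), had 134, 114, 24884 and 26431 counts in replicates 1 to 4. The Y-linked genes Ddx3y and Eif2s3y had 3409, 2573, 23 and 16, and 2493, 3709, 15 and 18. The labels record the sex as not collected. By edgeR 6 of 17337 genes varied more than genes of like abundance, Xist, Ddx3y, Eif2s3y, Sprr2h and Sprr2d (Benjamini-Hochberg adjusted p = 0.0389 for each) and the pseudogene Sprr2c-ps (adjusted p = 0.0469). At an unadjusted p under 0.05 there were 1068. The number was 79 without replicate 2, 0 without any of the others, 467 without a filter on counts and 0 with a filter of 100 counts, so it is not stable. The common biological coefficient of variation was 0.181 over the 4 libraries and 0.0616 without replicate 2.

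Several gene lists of T cell function varied more between libraries than random lists of like expression. The median SD of log2 TPM was 0.49 for the Th17 list, 0.55 for the Th1 list, 0.22 for glycolysis and 0.07 for the pan-T cell list, at the percentiles 100, 100, 99.99 and 36.9 of 10000 matched random lists. Of 29 lists 17 lay at or above percentile 95, and 9 without replicate 2. The 9 include the mitochondrial and small RNA lists, which went from percentile 86.7 to 100 and from 92.7 to 99 without replicate 2. Without that library the Th17 list had a median SD of 0.10 (percentile 99.1) and glycolysis one of 0.03 (percentile 13.4). Without replicate 2 the median SD went from 0.34 to 0.11 for the list linked to pathogenic Th17 cells and from 0.31 to 0.16 for the co-inhibitory receptors, which lay at percentiles 100 and 99.8, while the Treg list went from 0.33 to 0.06 and from percentile 99.7 to 33.6.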

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

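The tests of GC content and exon length, of depth, of keratinocytes, of another helper subset and of mixed-up reads were chosen only after the result was seen. The lists of other cell types were fixed before, but their use to test an explanation for replicate 2 was not part of the design. For each list mean, list difference, library measure and named gene, the gap between the highest or lowest library and its nearest neighbour was divided by the range over the 4 libraries. Values above Dixon's critical value at the 95% level are given here, on the log2 TPM scale for levels. Chance alone puts about 1 in 20 such measures past it, and the genes are not independent of each other. Of 43 list means, list differences and library measures 12 passed, 10 of them in replicate 2, and of 133 named genes 42 passed, 40 of them in replicate 2. Some named genes, such as Sprr2d and Mmp7, were chosen for their large changes in replicate 2 or their spread among the libraries. For those genes the chance rate does not hold, so the count of 42 cannot be set against it.

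Replicate 2 was lowest in the differences of the Th17 list from the Th1 (0.856), Th2 (0.908) and Treg (0.833) lists. It was lowest in the mean level of the Th17 list (0.952), the Th1 list (0.922), the Treg list (0.858), the list linked to non-pathogenic Th17 cells (0.850), glycolysis (0.965) and cholesterol and fatty acid synthesis (0.969). It was highest in the naive and central memory list (0.847). Replicate 4 was highest in the T cell activation list (0.940), and replicate 3 lowest in the TGF-beta list (0.862).

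Among cytokine, receptor and lineage genes replicate 2 was lowest in Il17a (0.898), Il17f (0.935), Ccr6 (0.943), Rora (0.904), Tmem176a (0.942), Tmem176b (0.949), Tbx21 (0.881), Stat4 (0.850), Stat6 (0.913), Ccr4 (0.940), Ctla4 (0.957), Pdcd1 (0.881), Il2ra (0.964), Il1rn (0.924), Jak2 (0.927), Crtam (0.878) and Trac (0.926). It was also lowest in the metabolic and stress genes Ldha (0.872), Cyp51 (0.967), Scd2 (0.934), Hspa5 (0.978) and Atf4 (0.937), and in Mmp7 (0.883), Itgb8 (0.968), Cdh17 (0.905), Il33 (0.944), Serpina3g (0.908) and Adgre1 (0.875). It was highest in Sprr2d (0.836), Sprr2f (1, the other libraries having 0 counts), Sprr2g (0.873), Sprr1a (0.891), Oas1a (0.902), Ccl3 (0.891), Ccr7 (0.933), Tcf7 (0.916), Hif1a (0.951), Dcn (0.906), Rplp1 (0.956) and Rpl8 (0.902). Replicate 1 was lowest in Tcrg-C2 (0.839), with 1 count against 5, 4 and 4, and replicate 4 highest in Hba-a2 (1), with 1 count against 0.

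Replicate 2 stood apart in 3907 genes, and 5 explanations were tested, some technical and some about which cells were sequenced. Removing each library's trends with GC content and exon length left 4106 genes past the test, 3532 of them shared, so these trends do not account for the pattern as a whole. Depth did not set replicate 2 apart, as its total of 37507204 lay below the 37746767 of replicate 4. Thinning all libraries to the smallest total, 33123029, left 3864 genes, of which 3724 were shared. With totals this close thinning could remove few calls whatever the cause, so it adds little. For cells of another lineage, no list of 7 other cell types had over 25.0% of its members higher in replicate 2 (4 of 62 members in all; 34 were tested, and the other 28 had under 10 counts over the 4 libraries), the highest share of tested members being 2 of 5, in the stromal list, and of the keratinocyte list 2 of 7 measured genes were higher (Ivl and Sfn) and 1 lower (Dsp), all but Ivl being present in the other libraries too, while Krt5 and Krt14 had 2 and 0 counts over the libraries. For a library of another helper subset, the highest share of tested members of the Th1, Th2, Treg and Tfh lists that were higher in replicate 2 was 2 of 10, in the Tfh list (4 of 44 over the 4 lists, with 24 lower), which argues against any of these 4 subsets as the whole cause. No other biological explanation was tested, since the design has 1 group. A difference in culture, animal or day of preparation stays open, as the labels give 4 biosamples under 1 donor identifier and no date of preparation.

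The 4 Y-linked genes and Xist divided the libraries, with Kdm5d at 951, 1306, 9 and 8 counts and Uty at 1449, 1497, 5 and 6 in replicates 1 to 4. If reads of replicate 2 were the only source of Y-linked counts in another library, the Y-linked genes would lie no higher there, as a share of their level in replicate 2, than the Sprr genes. The smallest share of the Y-linked genes was 0.525% (interval 0.387% to 0.697%), in replicate 4, against 0.0188% (interval 0.00228% to 0.0681%) for the Sprr genes. In replicate 3 the shares were 0.608% and 0.141%, and in replicate 1 they were 103% and 0.0644%, so reads from replicate 2 alone do not account for the Y-linked counts. Replicate 1 had 8302 Y-linked counts, so its share was bound to be high. Whether reads of replicate 1 reached replicates 3 and 4 was not tested. With Xist at 134, 114, 24884 and 26431 counts, the values argue against 1 animal as the source of all 4 libraries, whatever the donor identifier stands for. The spread behind the p-values is thus not technical alone. The values are those of male cells in replicates 1 and 2 and of female cells in replicates 3 and 4. The labels do not give the sex, so this was not tested. The division does not set replicate 2 apart. On the first principal component replicate 1 lay at −12.7, near −17.0 and −16.6 in replicates 3 and 4, against 46.3 in replicate 2.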

How the results depend on the processing

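Removal of GC content and exon length trends and thinning were chosen only after the result was seen; all other alternatives were planned. Of 169 alternatives of the design's results 151 stayed within their limits and 18 moved. The genes more variable than the trend numbered 6, with 0 under a filter of 100 counts, 467 without a filter and 0 with a non-robust prior, and between 0 and 79 leaving out 1 replicate at a time. The common biological coefficient of variation ranged from 0.0616 to 0.209 in this way, and the number of lists with a wide spread from 9 to 18. With DESeq2, 2, 15 and 3 genes were called in replicates 1, 3 and 4 in place of 0, and without a filter 17 in replicate 3. Leaving out each other library gave 0 to 68, 0 to 108 and 0 to 9 genes there, the highest without replicate 2, where fewer libraries and a smaller spread entered the fit. Leaving out replicate 1, 3 or 4 made the fits as small without such a rise, so fewer libraries alone do not account for it. The common biological coefficient of variation over the libraries left was 0.0616 without replicate 2 and 0.199 to 0.209 without another library. The rise thus went with the smaller spread, and other causes were not tested. In replicate 2 the called genes numbered 2864 to 4341, and 2830 to 3856 of them were shared with the 3907 reported. No paired analysis was possible because all 4 libraries form 1 group.

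Of 2606 alternatives for single genes and lists 2484 kept their direction and side of the threshold, 48 newly passed, 34 no longer passed, 38 counts or percentiles moved and 2 reversed. The 2 were Sprr2g and Sprr1a against 1 TPM, at −0.46 and −0.19 with limma, which averages logs, so that the 3 libraries near 0 outweigh replicate 2. The call of Il17re below 1 TPM was lost without replicate 1, 3 or 4, where its level stayed below (−0.64, −0.92 and −0.76 in log2), and that of Ifng above 1 TPM without replicate 3 or 4, where it stayed above (1.02 and 0.89). List counts of 0 are not among these alternatives; those of the Th17, B cell, mitochondrial and sex-linked lists rose above 0 in some settings. The filter of 10 summed counts left 17337 of 50600 genes to be tested, and for marker genes under 10 summed counts a change was not detectable.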

Other observations

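The tests of poly(A) selection and of reads shared between gene copies were chosen only after the result was seen, and the genes and gene groups in the next paragraphs were chosen after their values were seen. Ribosomal protein genes were higher together in replicate 2. Of 78 cytosolic ribosomal protein genes with a mean of at least 1 TPM, 70 were higher and 0 lower by edgeR, with a median log2 change of 0.27. The smallest change was 0.05, so none had a negative value. DESeq2 called 66 higher and 0 lower, and with its size factors in edgeR 69 were higher. With GC content and exon length trends removed 68 were higher, with a median of 0.25 and a lowest value of −0.08. These genes held 4.53% of all counts in replicate 2 and 3.77% to 3.94% in the others.

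Genes outside the named ones also differed in replicate 2 by over 2-fold in edgeR tests. Egln3, an oxygen-sensing prolyl hydroxylase gene, was lower at a log2 change of −2.06, Bnip3, a mitophagy receptor gene, at −1.37 and Ankrd37 at −1.40, while Hif1a was higher at 0.59. The chemokine receptor gene Cxcr4 was lower at −2.50, the protease inhibitor gene Timp1 at −2.24, Irf8, a transcription factor gene of immune cells, at −2.69 and Stra6, a retinol transporter gene, at −2.80. Spib, an Ets factor gene, was higher at 3.73, and the IL-1 decoy receptor gene Il1r2 at 2.30. Ermn and Ms4a4b were higher at 2.32 and 2.26. Between bases 92215799 and 92500493 of chromosome 3, 9 of 9 tested Sprr genes were higher. Of the 2 other tested genes in that stretch edgeR called 0, with 1 at an unadjusted p under 0.05, and DESeq2 called 0. Ivl, another gene of the cornified envelope, had 1.50 TPM in replicate 2 and 0 in the other libraries.

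Transcripts without a poly(A) tail were few in all 4 libraries, although the labels name the assay total RNA-seq. Small RNA genes held 0.0259% to 0.0353% of counts, and linker histone genes, whose main transcripts lack a poly(A) tail, had a median of at most 1.88 TPM and at most 1.31% of the cell cycle median. Those values are consistent with poly(A) selection, which the title of the linked protocol also names. Reads shared between near-identical copies, the other explanation tested, would lower core histones but not the linker histones, which differ in sequence, and core histones were no lower, with medians of 1.13 to 2.67 TPM. Small RNA genes were not part of that comparison, so their low share does not tell these explanations apart. Loss of short transcripts was not tested, and Hist1h1c, Hist1h2bc and Hist1h4i stood apart from the rest at 38.3 ± 7.53, 38.7 ± 3.24 and 27.4 ± 1.39 TPM (SD, n = 4), and no biological explanation was tested.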
